A study of Mus musculus with 10 samples.

How the data were processed

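RNA from fasted male mouse livers was measured on 10 Affymetrix whole-transcript arrays, with 1 array per liver sample and no pooling stated in the labels. The mice had received an adeno-associated virus with a liver promoter carrying either GFP or the follistatin isoform FST288, about 2 weeks before. Per the labels, RNA was extracted with an organic reagent and cleaned on columns with DNase, and 500 ng of RNA gave 5.5 µg of biotin-labelled single-stranded DNA for each array.

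The deposited table holds log2 values that the authors made with RMA in Affymetrix Expression Console, which corrects the background, sets all arrays to the same distribution and summarises the probes of each transcript cluster. The version of that program is not stated. The base of the logarithm is not written in the file; log2 is read from the use of RMA and from the range of the values, 0.64 to 13.21. The table has 41345 transcript clusters per array and 0 missing values. Array medians lay between 2.71 and 2.75. An array gives no counts, so no depth can be stated, and the number of arrays limits the precision.

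Transcript clusters were matched to mouse gene symbols with the supplied gene table. Of the clusters, 23521 were listed with 1 symbol, 1814 with several symbols and 16010 were not listed. Clusters with several symbols were left out, as were the unlisted clusters, which were tested in another fit of all 41345 clusters. For the 1082 genes with several clusters, the cluster with the highest mean over all arrays was used. This left 22180 genes, and dim genes were not filtered out. The supplied annotation of the assembly GRCm38.p6 was used for the order of genes along chromosomes alone.

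The groups were wild-type mice on a high-fat diet with GFP (HFD GFP, n = 3) or FST288 (HFD FST288, n = 3), and mice labelled LTKO with GFP (LTKO GFP, n = 2) or FST288 (LTKO FST288, n = 2). A linear model with 1 mean per group was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3, and its variances were moderated by eBayes with an intensity trend. The fit had 6 residual and 7.155 prior degrees of freedom. The 5 contrasts were FST288 against GFP in HFD livers, the same in LTKO livers, the average of these effects, their difference (LTKO minus HFD) and LTKO GFP against HFD GFP. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over the 22180 genes within a contrast. A gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors of the fit, and errors of group means are SD.

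The lists were 31 sets of genes for liver metabolism, signalling, stress and inflammation and 16 sets of cell type markers, 47 in all. They were fixed before the data were examined, as were the contrasts, the tests and the rule for named genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with p adjusted over the 47 lists within a contrast. For each list the members called over all genes were counted, and those called when p was adjusted over the list alone. The labels do not say in so many words that each array is a separate animal, so the p-values measure the spread between these samples.

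The rule for named genes took, in each contrast, the 10 called genes with the largest rise and the 10 with the largest fall. It left out predicted and unnamed loci and small nucleolar RNA, microRNA and olfactory receptor genes. It filled up fewer than 5 in a direction by unadjusted p. It added the 4 members of each list with the smallest p, and always Fst, Irs1, Irs2, Foxo1, G6pc, Pck1, Srebf1, Igfbp1, Inhba, Inhbb, Inhbc, Inhbe, Fstl3 and Fgf21. Genes outside the rule are marked in the text as chosen after their values were seen.

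The call procedure was tested on simulated data made with the gene means and spreads of these arrays, with 200 changed genes in each of 5 runs. At the size of the HFD groups it recovered 42.1% of the changes of 0.5 on the log2 scale and 98.8% of those of 1; at the size of the LTKO groups, 20.0% and 88.7%. False calls made up 6.74% and 6.48% of the genes called. A list shifted by 0.5 on the log2 scale was found in 20 of 20 runs with the preset and with the estimated correlation. Over these runs the preset correlation also called 4 lists that had not been shifted, and the estimated correlation 0. Each gene was given the same spread in all groups of the simulated data. The figures for the LTKO groups therefore do not cover LTKO livers that vary more than the HFD livers. Genes were drawn independently of each other in the simulated data. The runs therefore hold no inter-gene correlation and cannot choose between the preset and the estimated correlation for the real arrays.

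Before the data were examined, 25 alternatives were planned. They changed the arrays in the fit, the moderation of the variances, array weights, the normalization, filters on dim genes, the handling of several clusters per gene, the features tested, the thresholds, a replicate block, the set test and each replicate left out in turn. After seeing the data, a covariate for pancreatic acinar genes was added, with a fit without the 2 arrays high in these genes, and Fst, the cargo of the vector, was left out of the lists and of the overlap of the backgrounds. Where a left-out array leaves 1 array in a group, that array is assumed to vary like the other groups. The p-values and counts of such fits then do not measure the spread within that group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.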

Results

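Transcript levels were measured in 10 mouse liver samples on 1 array each, as RMA values on the log2 scale for 22180 named genes. The labels do not say in so many words that each sample is a separate animal. The livers came from fasted males about 2 weeks after an adeno-associated virus that expresses its cargo in hepatocytes. The cargo was either GFP, the control, or FST288, an isoform of follistatin, a secreted protein that binds and blocks activins and related ligands. Wild-type mice on a high-fat diet gave 3 HFD GFP and 3 HFD FST288 arrays. Mice labelled LTKO gave 2 LTKO GFP and 2 LTKO FST288 arrays. The labels do not spell out LTKO; as background, the name is used for mice whose livers lack Irs1, Irs2 and Foxo1, that is, the adaptors of the insulin receptor and the transcription factor that insulin shuts off. The diet of the LTKO mice is not stated. Array medians lay between 2.71 and 2.75, and the lowest mean correlation of an array with its own group was 0.989. The median SD within a group was 0.16 over all genes.

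The vector's own gene and the targeted genes were read first. Follistatin transcript (Fst, transcript cluster 17296344) rose with the FST288 vector in both backgrounds. In HFD livers it went from 5.27 ± 0.06 to 6.35 ± 0.52 (SD, n = 3 and 3), 2.11-fold higher with an adjusted p of 0.015. In LTKO livers it went from 5.35 ± 0.06 to 6.79 ± 0.08 (n = 2 and 2), 2.72-fold higher with an adjusted p of 0.0307. The LTKO and HFD livers with GFP differed in Fst by 0.08 ± 0.21 (adjusted p = 0.878). Irs1 (17224878) was 3.40-fold lower in LTKO GFP than in HFD GFP livers, at 3.15 ± 0.06 against 4.91 ± 0.20 (adjusted p = 5.21e-06). Irs2 (17507374) was 2.31-fold lower, at 2.94 ± 0.60 against 4.15 ± 0.12 (adjusted p = 0.00409). Foxo1 (17397497) was 3.21-fold lower, at 5.04 ± 0.16 against 6.72 ± 0.12 (adjusted p = 1.49e-06). With the mean of a gene's clusters in place of the highest, the changes in Irs1 and Foxo1 were -0.89 and -0.90. The LTKO GFP means of Irs1 and Irs2 lie near the median of named genes, 3.10 to 3.17 per array, a level at which a fold is not an exact measure. The FST288 vector gave log2 changes between -0.29 and 0.12 in Irs1, Irs2 and Foxo1, with adjusted p from 0.526 to 0.968; leaving out 1 array, they ran from -0.55 to 0.30 without a call, both ends in Irs2 of LTKO livers (without LTKO GFP replicates 1 and 2). A cluster's value does not separate vector transcripts from those of the mouse gene. The Fst call in HFD livers was lost without HFD GFP replicate 1 (adjusted p = 0.0511), 2 (0.0621) or 3 (0.0676) and without HFD FST288 replicate 3 (0.0955). In LTKO livers it was lost without HFD GFP replicate 1 (0.0597), 2 (0.0606) or 3 (0.0625), HFD FST288 replicate 3 (0.0655), LTKO GFP replicate 1 (0.0844) or 2 (0.118) and LTKO FST288 replicate 2 (0.0699). The Irs2 call was lost without LTKO GFP replicate 1, where the change was -0.79 (adjusted p = 0.0713).

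**Figure D1:**
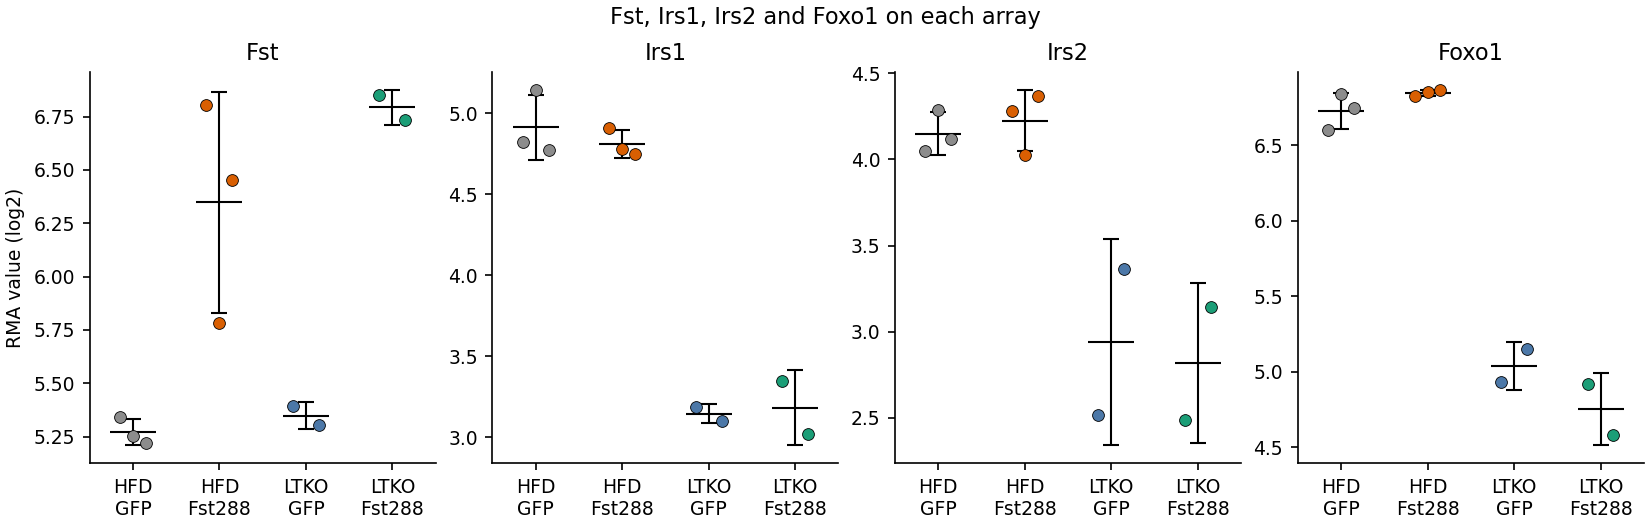
Array values (log2 RMA) of Fst, Irs1, Irs2 and Foxo1 in the 4 groups, with a point per array and the group mean ± SD. Fst averages 6.35 and 6.79 in the FST288 groups against 5.27 and 5.35 with GFP, and Irs1, Irs2 and Foxo1 are lower in the LTKO groups.

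The first comparison asks which liver transcripts differ with follistatin in mice on a high-fat diet. Csad, an enzyme of taurine synthesis, was 3.86-fold lower with FST288, at 4.54 ± 0.10 against 6.49 ± 0.16 (SD, n = 3 and 3; adjusted p = 1.58e-06). Srebf1, the gene of the lipogenic transcription factor SREBP-1, fell 2.26-fold (adjusted p = 0.00108), and Hmgcs1, an early enzyme of cholesterol synthesis, fell by 0.87 ± 0.08 on the log2 scale (adjusted p = 0.000179). Further falls were 3.70-fold in Mug2 and 3.66-fold in Mug-ps1, of a family of plasma protease inhibitors and its pseudogene, 2.38-fold in Abcd2, a peroxisomal transporter, 1.95-fold in Abcc3, a bile acid and conjugate exporter, and 1.78-fold in Etnppl, an enzyme of phosphoethanolamine breakdown. Rises were 2.91-fold in the hepatocyte transcription factor Onecut1, 2.73-fold in the transcription factor Zbtb16, 2.62-fold in E2f8, 2.52-fold in the cytochrome P450 Cyp4a12a and in Pls1, 2.42-fold in the cell cycle inhibitor Cdkn1a, 2.38-fold in the mitochondrial carrier Slc25a30, 2.32-fold in Txnip and 2.24-fold in the steroid hydroxylase gene Cyp17a1. Ugt2b37, a glucuronosyltransferase, was 3.22-fold higher by limma (adjusted p = 0.048), a call lost in 8 of 10 leave-one-out fits. Its GFP mean was 2.48, a level at which a fold is not an exact measure. The values of Etnppl here and of Mid1ip1 and Gpam among the lipid genes lie outside the rule for named genes and were chosen after they were seen.

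Among metabolic groups in HFD livers, the glycolysis list leaned upwards. Of its 15 measured members 1 rose over all genes, Khk, the first enzyme of fructose use (log2 change 0.51 ± 0.08, adjusted p = 0.009), and 7 rose adjusted over the list alone. Its camera test gave an adjusted p of 9.98e-06, and an adjusted p = 0.0702 with an estimated correlation. Of 24 measured fatty acid synthesis genes, Lpin1 (0.86) and Txnip (1.22) rose, while Srebf1 (-1.18), Mid1ip1 (-0.73), Elovl5 (-0.58) and Gpam (-0.54) fell; adjusted over the list alone 7 rose and 6 fell, and the list was not called (adjusted p = 0.792). The change in Mid1ip1 was -0.18 with the mean of a gene's clusters (limma, adjusted p = 0.655). Its call was lost in each of the 6 fits that left out an HFD array. The change in Elovl5 was -0.37 with an acinar covariate chosen after seeing the data (limma, adjusted p = 0.449). In the cholesterol synthesis list 1 of 19 members fell, Hmgcs1, and 6 adjusted over the list alone (camera down, adjusted p = 0.0014; adjusted p = 0.499 with an estimated correlation). Of 29 fatty acid oxidation genes 3 rose, Cyp4a14 (0.63), Cyp4a31 (1.18) and Angptl4 (0.51), and adjusted over the list alone 7 rose and 4 fell (camera up, adjusted p = 0.00271; adjusted p = 0.481 with an estimated correlation). Cyp4a14 was at 0.37 with the acinar covariate (adjusted p = 0.548). The lipid droplet genes G0s2 (1.03, and 0.59 with the mean of its clusters) and Plin5 (0.67) rose, while their list of 18 was not called (adjusted p = 0.093; 4 rose and 2 fell adjusted over the list alone). In the bile acid list of 24, the synthesis enzymes Hsd3b7 (-0.57) and Cyp8b1 (-0.54) fell with Abcc3, and the exporter Abcb11 (0.42) rose; the list was not called (adjusted p = 0.903; 7 rose and 6 fell adjusted over the list alone). In oxidative phosphorylation no member passed over all genes by limma, 11 of 31 rose and 1 fell adjusted over the list alone, and camera called it up (adjusted p = 2.2e-08; adjusted p = 0.481 with an estimated correlation). Its members Cox5b and Sdhd had changes of 0.58 (adjusted p = 0.155) and 0.30 (0.0812), and Cox5b was called without HFD FST288 replicate 1 (0.79, adjusted p = 0.0219). Over all other settings the change in Cox5b ran from 0.14 to 0.79.

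Glucose production genes gave no call in HFD livers. G6pc, the last enzyme of glucose release, changed by 0.25 ± 0.14 (adjusted p = 0.525) and Pck1, an early enzyme of gluconeogenesis, by -0.01 ± 0.10 (adjusted p = 0.985). Of 18 gluconeogenesis genes 1 was higher and 1 lower adjusted over the list alone, and the list was not called (adjusted p = 0.297). The FoxO1-responsive list of 25 was called up (adjusted p = 0.048; adjusted p = 0.506 with an estimated correlation), but Fst, the cargo of the vector, is a member. Without Fst, a test chosen after seeing the data, the list was not called (adjusted p = 0.1). Besides Fst, its members Cdkn1a, Txnip and Mttp, a lipoprotein assembly protein, rose, while Igfbp1, a classical FoxO1 target, changed by -0.10 (adjusted p = 0.92). Adjusted over the list alone, 5 of its members rose with Fst counted and 4 without it, and 1 fell. Among insulin-induced genes Lpin1 and the feedback inhibitors of growth factor signalling Dusp6 (0.81) and Spry4 (0.67) rose and Srebf1 fell; Dusp6 was at 0.40 with the mean of its clusters (adjusted p = 0.288). That list of 14 was not called by camera (adjusted p = 0.172), and 4 rose and 1 fell adjusted over the list alone. The calls of Dusp6 and Spry4 were lost in each of the 6 fits that left out an HFD array.

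Among ligands that follistatin can bind, Inhba, the activin A subunit gene, rose 1.97-fold in HFD livers (adjusted p = 0.0182), a call lost in 4 leave-one-out fits (adjusted p from 0.0575 to 0.103). The changes were 0.36 in Inhbb (adjusted p = 0.604), which was 0.21 without HFD FST288 replicate 2 (0.885), -0.39 in Inhbc (0.265), -0.40 in Inhbe (0.16) and 0.04 in the related binding protein Fstl3 (0.953). The BMP-responsive genes Hamp, encoding the iron hormone hepcidin, and Atoh8 fell by 0.77 and by 0.66 on the log2 scale (adjusted p = 0.0456 and 0.0364). Each of these calls was lost in 5 of the 6 fits that left out an HFD array, with adjusted p from 0.11 to 0.191 for Hamp, kept without HFD FST288 replicate 1, and from 0.0719 to 0.16 for Atoh8, kept without HFD GFP replicate 2. The change in Hamp was -0.57 without HFD FST288 replicate 2 and -0.29 with an acinar covariate chosen after seeing the data. Neither the ligand and receptor list of 32 (adjusted p = 0.431; 3 rose, Fst among them, and 2 fell adjusted over the list alone) nor the target list of 25 (adjusted p = 0.172; 1 rose and 4 fell adjusted over the list alone) was called. Fgf21, a fasting hormone, changed by -0.10 (adjusted p = 0.945).

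Single genes of zonal and detoxifying lists also changed in HFD livers. The pericentral hepatocyte markers Oat (-0.75), Lect2 (-0.71) and Glul (-0.38) fell, 3 of 12 members and 4 adjusted over the list alone, and camera called the list down (adjusted p = 6.04e-05; adjusted p = 0.0702 with an estimated correlation). Cyp3a11, a drug-metabolising P450, fell by 0.84, while Cyp2c29 (0.53) and Aldh1a1 (0.56) rose; their list of 25 was not called (adjusted p = 0.265; 6 rose and 2 fell adjusted over the list alone), and Cyp2c29 was at 0.25 with the mean of its clusters (adjusted p = 0.237). The glutathione synthesis genes Gclc (-0.33) and Gclm (-0.36) fell, calls lost in each of the 6 fits that left out an HFD array. Their list of 25 was not called by camera (adjusted p = 0.265), and 1 rose and 3 fell adjusted over the list alone. Of 21 lipoprotein genes, 2 rose, among them Mttp (0.48), and 3 fell, among them Sort1 (-0.96) and Apoa1 (-0.40), with 4 and 7 adjusted over the list alone and no call (adjusted p = 0.105); Sort1 was at -0.44 with the mean of its clusters (adjusted p = 0.138). Igfbp2, an IGF carrier, fell by 0.82. In the acute phase list of 27, Il1r1 (0.95) and Steap4 (0.67) rose and Itih3 (-0.75) fell; adjusted over the list alone 6 rose and 1 fell (camera up, adjusted p = 0.00271; adjusted p = 0.499 with an estimated correlation). The p53 targets Cdkn1a and Eda2r (0.85, from a GFP mean of 2.18, under the array medians of named genes) rose, 2 of 17 and 4 adjusted over the list alone (camera up, adjusted p = 0.000481; adjusted p = 0.481 with an estimated correlation), and Ccng1 had a change of 0.78 (adjusted p = 0.128), called without HFD GFP replicate 2 (1.03, adjusted p = 0.0486) and without either LTKO FST288 replicate. The calls in Eda2r and Cdkn1a were lost in 8 and 5 of 10 leave-one-out fits. Of 19 male-predominant genes Cyp4a12a rose, with 4 higher and 1 lower adjusted over the list alone. Camera called that list up (adjusted p = 0.0014, and 0.506 with an estimated correlation). The ribosomal protein list of 23 was called up with 1 member adjusted over the list alone (adjusted p = 0.048; adjusted p = 0.506 with an estimated correlation).

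Pancreatic acinar genes moved with this comparison on a subset of arrays. The median of 9 acinar markers was 8.59 on HFD FST288 replicate 2 and 7.48 on replicate 3, against 2.59 on replicate 1 and 2.55 to 2.81 on the HFD GFP arrays. The marker list was called up (adjusted p = 8.4e-09; adjusted p = 0.481 with an estimated correlation), and Cpb1, a pancreatic carboxypeptidase, had a log2 change of 4.63 ± 1.19 (adjusted p = 0.0982). This is not an exact measure: the GFP mean was 2.10, and the change averages 1 array at 2.52 and 2 at 9.31 and 8.36. It was 3.34 without HFD FST288 replicate 2 and 6.74 without replicate 1 (adjusted p = 0.348 and 3.18e-07). With an acinar covariate, or without replicates 2 and 3, both chosen after seeing the data, 4 lists were no longer called by camera. With the covariate they were cholesterol synthesis (adjusted p = 0.424), acute phase (0.698), male-predominant genes (0.131) and the acinar list (0.931). Without replicates 2 and 3, where 1 array is left in the group, they were the same lists. The loss of the acinar list was fixed in advance, since both settings were built from its markers.

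In all, 221 genes differed with FST288 in HFD livers at an adjusted p under 0.05 by limma, 128 higher and 93 lower (102 and 115 with quantile normalization), and 2672 had an unadjusted p under 0.05. The median of 73 small nucleolar RNA genes was 6.76 to 6.98 on the HFD FST288 arrays and 6.12 to 6.61 on the HFD GFP arrays. Camera called 11 of 47 lists, none of them with an estimated correlation, and fry called 2, glycolysis (adjusted p = 0.000734) and pericentral markers (0.00384). The count of genes was 122, 129 and 99 without HFD GFP replicates 1, 2 and 3, 80 and 91 without HFD FST288 replicates 2 and 3, 35 with the acinar covariate and 6 without both acinar-high arrays. Of the 57 genes called and named for HFD livers, 27 were called in every leave-one-out fit, among them Csad, Etnppl, Srebf1, Hmgcs1, Cyp4a12a, Slc25a30, Onecut1, Txnip, G0s2 and Oat. The calls lost were 20, 23 and 24 without HFD GFP replicates 1, 2 and 3, 17, 24 and 25 without HFD FST288 replicates 1, 2 and 3, and 2 without either LTKO GFP replicate. With the acinar covariate 40 of the 57 calls were lost, and without both acinar-high arrays 52. In 36 of the 40 and 50 of the 52 the change stayed within 1.5 times of its value; those that shrank more were Hamp and Cyp4a14 in both settings and Abcd2 (-0.78) and Elovl5 with the covariate. The 57 genes were picked by calls that used all 3 HFD FST288 arrays, so replicate 1 had to go with the others. Stable sizes were largely fixed by that choice. In 200 genes picked without replicate 1, its median size was 0.40 to 0.48, against 0.79 to 0.80 on the arrays they were picked from. Among lists, fatty acid oxidation was lost without HFD GFP replicate 1 (camera, adjusted p = 0.0701) and acute phase without HFD FST288 replicate 2 (0.0549). The FoxO1-responsive list was lost without HFD GFP replicate 1 (0.169), HFD FST288 replicate 1 (0.13) and LTKO FST288 replicates 1 (0.0575) and 2 (0.0573). With Fst left out of the lists, 9 were called, without the FoxO1-responsive and ribosomal (0.0527) lists. The ribosomal list was lost without HFD GFP replicates 2 (0.0584) and 3 (0.129), HFD FST288 replicate 1 (0.124) and LTKO FST288 replicates 1 (0.0509) and 2 (0.0511).

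**Figure D2:**
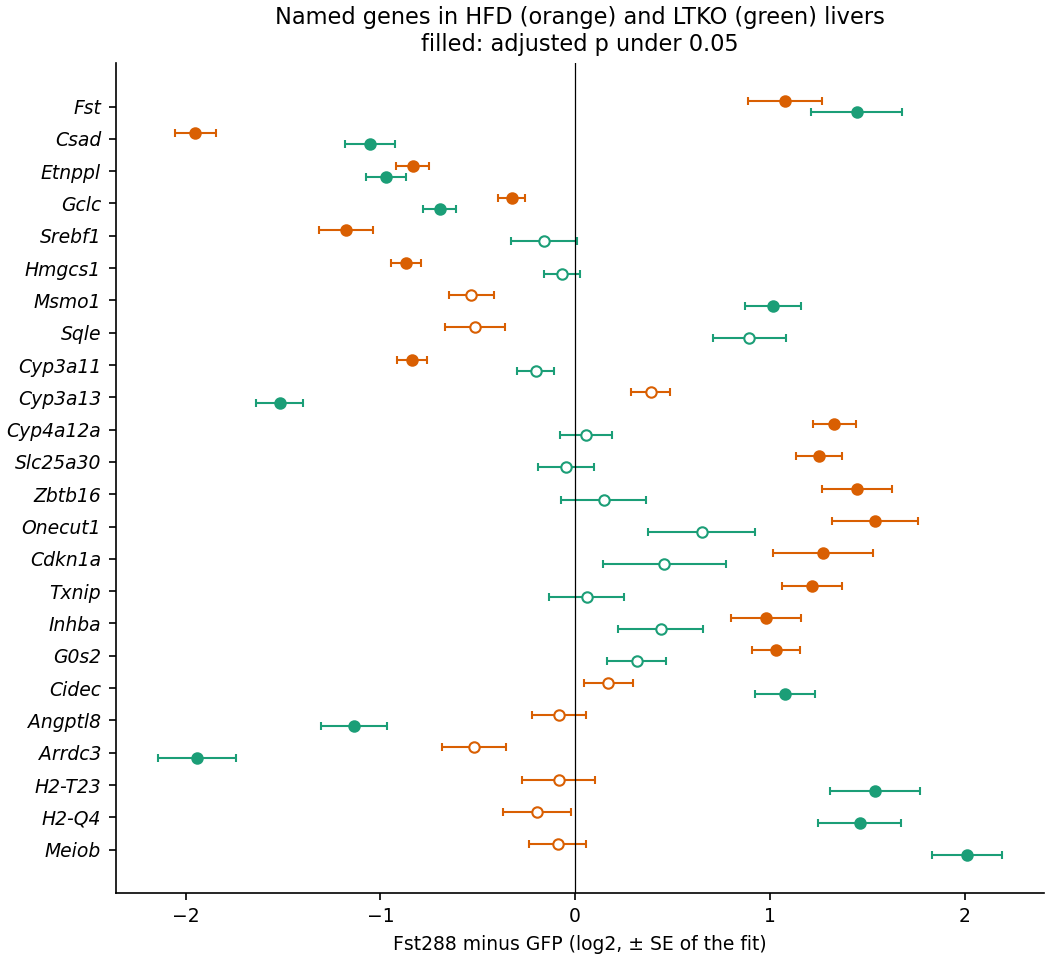
Log2 change with FST288 ± SE of the fit for 24 named genes in HFD livers (orange) and LTKO livers (green), with filled points for an adjusted p under 0.05. Csad and Etnppl are lower and Fst is higher in both backgrounds, and Srebf1 has changes of -1.18 in HFD and -0.16 in LTKO livers, a difference with an adjusted p of 0.0882.

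The second comparison asks the same of LTKO livers. Arrdc3, an arrestin-domain protein, was 3.84-fold lower with FST288, at 6.91 ± 0.40 against 8.85 ± 0.49 (SD, n = 2 and 2; adjusted p = 0.00137). Serpina4-ps1, a pseudogene of the serine protease inhibitors, fell 3.74-fold, Cyp3a13, a drug-metabolising P450, 2.87-fold, Angptl8, an insulin-responsive regulator of lipoprotein lipase, 2.20-fold, Csad 2.08-fold and Etnppl 1.96-fold. Rises included 4.45-fold in the MHC class II gene H2-Eb1, 4.03-fold in Meiob, a meiotic DNA-binding protein that went from 2.84 ± 0.35, where a fold is not an exact measure, to 4.85 ± 0.07, 2.90-fold in H2-T23 and 2.76-fold in H2-Q4, both MHC class I genes. The call in H2-Eb1 was lost in 8 of 10 leave-one-out fits (adjusted p from 0.0634 to 0.173), and its log2 change of 2.15 was 1.45 without LTKO FST288 replicate 2 (adjusted p = 0.122). H2-Q4 was at 0.90 on the log2 scale with the mean of its clusters (adjusted p = 0.117). Cidec, a lipid droplet protein, rose 2.11-fold and Msmo1, an enzyme of cholesterol synthesis, 2.02-fold. Scd1, the desaturase of fat synthesis, fell by 0.55, Gclc by 0.70 and the sterol exporter gene Abcg8 by 0.68 on the log2 scale. The peroxisomal thiolase Acaa1b (0.68) and the receptor gene Tgfbr2 (0.79) rose. Of 10 leave-one-out fits, the call was lost in 8 for Scd1, 8 for Abcg8, 9 for Tgfbr2 and 1 for Acaa1b.

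Immune lists leaned upwards in LTKO livers, and LTKO FST288 replicate 2 stood apart in them. Of 11 MHC class I genes 2 rose, and 5 adjusted over the list alone (camera up, adjusted p = 6.98e-11; adjusted p = 0.341 with an estimated correlation). Of 35 interferon-stimulated genes 12 rose adjusted over the list alone (camera, adjusted p = 6.98e-11, and 0.341 with an estimated correlation). Igtp, an interferon-induced GTPase, had a log2 change of 2.46 ± 0.74 (adjusted p = 0.271). It was 0.62 without LTKO FST288 replicate 2 and 4.31 without replicate 1. Such a fit leaves 1 array in the group and does not measure the spread between its samples. Of 19 macrophage markers 8 rose adjusted over the list alone (adjusted p = 4.07e-10; adjusted p = 0.341 with an estimated correlation), where the macrophage receptor genes Marco and Adgre1 had changes of 1.93 (adjusted p = 0.179) and 1.39 (0.149). Without LTKO FST288 replicate 2 these were 0.87 and 0.79, and without replicate 1 they were 2.98 and 1.98. The macrophage median was 6.60 on LTKO FST288 replicate 2 and 5.48 on replicate 1, against 5.36 on each LTKO GFP array. The interferon median was 5.17 on replicate 2 and 4.50 on replicate 1, against 4.24 and 4.22, and the MHC class I median 6.67 and 5.76, against 5.14 and 4.94. The T and NK cell markers were called up (adjusted p = 0.00475; adjusted p = 0.403 with an estimated correlation) without any of the 16 passing adjusted over the list alone. The acute phase list of 27 was called up with 5 members adjusted over the list alone (adjusted p = 0.00274; adjusted p = 0.341 with an estimated correlation); Saa2 had a change of 2.37 (adjusted p = 0.0703) and Orm2 of 0.96 (0.187). Without LTKO FST288 replicate 1 they were 2.70 and 1.35, and without replicate 2 they were 2.03 and 0.57. Saa2 was called without HFD FST288 replicate 1.

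Stress, sex-biased and lipid lists were called in LTKO livers as well. The unfolded protein response list leaned downwards, with 4 of 24 members lower adjusted over the list alone (adjusted p = 7.28e-08; adjusted p = 0.341 with an estimated correlation); its sensor Ern1 had a change of -0.59 (adjusted p = 0.142) and the chaperone gene Hspa5 of -0.49 (0.197). Ern1 was at -0.80 without LTKO GFP replicate 1 and -0.39 without replicate 2. Of 17 female-predominant genes Cyp2a4 rose (1.09), and 3 rose adjusted over the list alone (camera, adjusted p = 3.3e-06, and 0.136 with an estimated correlation). Cyp2b9 had a change of 3.23 ± 0.58 (adjusted p = 0.0519) and was called in 6 of 25 other settings. It went from 1.80 without LTKO FST288 replicate 2 to 4.66 without replicate 1. Its GFP mean was 3.11, near the array medians of named genes. Of 19 cholesterol synthesis genes Msmo1 rose, and 4 adjusted over the list alone (adjusted p = 0.000376; adjusted p = 0.341 with an estimated correlation). Cidec rose among 18 lipid droplet genes, 3 adjusted over the list alone (camera up, adjusted p = 0.00857, and 0.341 with an estimated correlation). The median over that list was nonetheless lower with FST288, at 5.66 and 5.88 against 5.96 and 5.93 on the LTKO GFP arrays. Acaa1b rose among 29 fatty acid oxidation genes, 1 adjusted over the list alone (adjusted p = 0.00969; adjusted p = 0.341 with an estimated correlation).

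Of 25 FoxO1-responsive genes Fst rose and Angptl8 fell in LTKO livers, with 6 and 1 adjusted over the list alone (adjusted p = 0.00332; adjusted p = 0.341 with an estimated correlation). Without Fst, the cargo of the vector, none of the other 24 rose over all genes by limma and 5 did adjusted over the list alone, and camera still called the list up (adjusted p = 0.016; adjusted p = 0.434 with an estimated correlation). Igfbp1 had a change of 1.42 ± 0.29 (adjusted p = 0.104) and was called in 3 of 25 other settings. It went from 0.78 without LTKO GFP replicate 1 to 2.05 without replicate 2. The change was 0.57 in G6pc (adjusted p = 0.278), 0.45 in Pck1 (0.237) and -1.29 in Fgf21 (0.271). Fgf21 was at -0.44 without LTKO FST288 replicate 1 and -2.15 without replicate 2. G6pc was at 0.28 without LTKO GFP replicate 1 and 0.87 without replicate 2. Pck1 was at 0.26 without LTKO FST288 replicate 2 and 0.64 without replicate 1. Srebf1 changed by -0.16 (adjusted p = 0.823). The activin subunit genes changed by 0.44 in Inhba (adjusted p = 0.54), -0.25 in Inhbb (0.841), -0.66 in Inhbc (0.214) and -0.53 in Inhbe (0.237), and Fstl3 by -0.04 (0.962). Inhbc and Inhbe were at -0.34 and -0.29 without LTKO FST288 replicate 1, and at -0.98 and -0.77 without replicate 2. Inhba was at 0.28 without LTKO FST288 replicate 1, and Inhbb at -0.74 and 0.24 without LTKO GFP replicates 1 and 2. Camera also called xenobiotic metabolism up (adjusted p = 0.0451; adjusted p = 0.341 with an estimated correlation), where Cyp2a4 rose and Cyp3a13 fell, with 4 of 25 higher and 1 lower adjusted over the list alone. It called p53 targets up (adjusted p = 0.0238; adjusted p = 0.403 with an estimated correlation), with 1 of 17 higher and 1 lower adjusted over the list alone and a change of 1.01 in Btg2 (adjusted p = 0.138). Oxidative phosphorylation was called down (adjusted p = 0.006; adjusted p = 0.505 with an estimated correlation), with 1 of 31 lower adjusted over the list alone and -0.49 in Cox8a (adjusted p = 0.135). The hepatocyte markers were called down by camera (adjusted p = 0.0221, and 0.341 with an estimated correlation), with 2 of 9 lower adjusted over the list alone. Their median did not fall, at 11.59 and 11.75 on the LTKO FST288 arrays against 11.49 and 11.69 on the LTKO GFP arrays.

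In all, 37 genes differed with FST288 in LTKO livers by limma, 22 higher and 15 lower, and 2213 had an unadjusted p under 0.05. With only the 4 LTKO arrays in the fit, limma called 0 genes and 1665 had an unadjusted p under 0.05. Camera called 15 of 47 lists, none with an estimated correlation, and fry called 0, with a lowest adjusted p of 0.117. The count of genes was 23, 21 and 23 without HFD GFP replicates 1, 2 and 3, 22, 23 and 21 without HFD FST288 replicates 1, 2 and 3, and 237 without LTKO FST288 replicate 1. It was 16 without both acinar-high HFD arrays and 23 with the acinar covariate. Of the 23 genes called and named here, 7 were called in every leave-one-out fit: Csad, Etnppl, Cyp3a13, Arrdc3, Meiob, Serpina4-ps1 and Gclc. The calls lost were 6, 8 and 6 without HFD GFP replicates 1, 2 and 3, 7, 5 and 7 without HFD FST288 replicates 1, 2 and 3, 10 and 13 without LTKO GFP replicates 1 and 2, and 2 and 9 without LTKO FST288 replicates 1 and 2. The MHC class I, interferon, macrophage, unfolded protein and female-predominant lists were called in all 10 leave-one-out fits. Without LTKO FST288 replicate 2, the acute phase (adjusted p = 0.155), T and NK cell (0.497), FoxO1-responsive (0.227), lipid droplet (0.102) and xenobiotic (0.0999) lists were lost. Without replicate 1, cholesterol synthesis (0.119), p53 targets (0.295), oxidative phosphorylation (0.0725) and hepatocyte markers (0.218) were lost. Without LTKO GFP replicate 1, fatty acid oxidation (0.163), lipid droplet (0.122), FoxO1-responsive (0.228), p53 (0.545) and oxidative phosphorylation (0.505) lists were lost, and without LTKO GFP replicate 2, the xenobiotic (0.449) and hepatocyte (0.191) lists. The xenobiotic list was also lost without HFD GFP replicates 1 (0.0524) and 3 (0.0557).

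The third comparison asks what follistatin did in both backgrounds. Genes called in both and in the same direction were Fst, the chemokine gene Ccl9 and 9030619P08Rik among rises, and Csad, Etnppl, Gclc, the aldehyde oxidase gene Aox3 and Tcf24 among falls; Ccl9, Aox3, 9030619P08Rik and the HFD value of Tcf24 were chosen after they were seen. Ccl9 rose by 0.55 in HFD and 0.68 in LTKO livers, and 9030619P08Rik by 1.13 and 1.61. Aox3 had log2 changes of -0.59 and -0.69, and Tcf24 of -0.77 and -1.07. These 3 rises and 5 falls compare with 0.127 and 0.0629 expected if the calls were independent, and no gene was called in opposite directions. Both contrasts share the variance of each gene and dim genes were not filtered out, so chance alone may give more. Fst is the cargo of the vector, and without it the 2 rises and 5 falls compare with 0.12 and 0.0587. Of the 8 genes, Csad and Etnppl were called in both backgrounds in each of the 10 leave-one-out fits. The number of the 8 that stayed called in both was 4, 3 and 4 without HFD GFP replicates 1, 2 and 3, 5, 4 and 3 without HFD FST288 replicates 1, 2 and 3, 4 without either LTKO GFP replicate and 5 without LTKO FST288 replicate 2. It was 3 with the acinar covariate and 2, Csad and Fst, without both acinar-high arrays. Genes outside the 8 were shared in 3 leave-one-out fits. Without HFD FST288 replicate 1, 3 rises and 3 falls were shared. Without LTKO FST288 replicate 1, 9 rises and 7 falls were shared and 5 genes were called in opposite directions; without LTKO FST288 replicate 2 the numbers were 7, 8 and 1. Opposite calls also came to 6 and 2 without LTKO GFP replicates 1 and 2, 1 without HFD FST288 replicate 1, and 1 with quantile normalization or median centring. Across all genes, which are not independent replicates, the effects had a Pearson r of -0.077 and a Spearman rho of -0.109. Among the 221 genes called in HFD livers, 147 had the same sign in LTKO livers, and among the 37 called in LTKO livers 20 had the same sign in HFD livers.

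**Figure D3:**
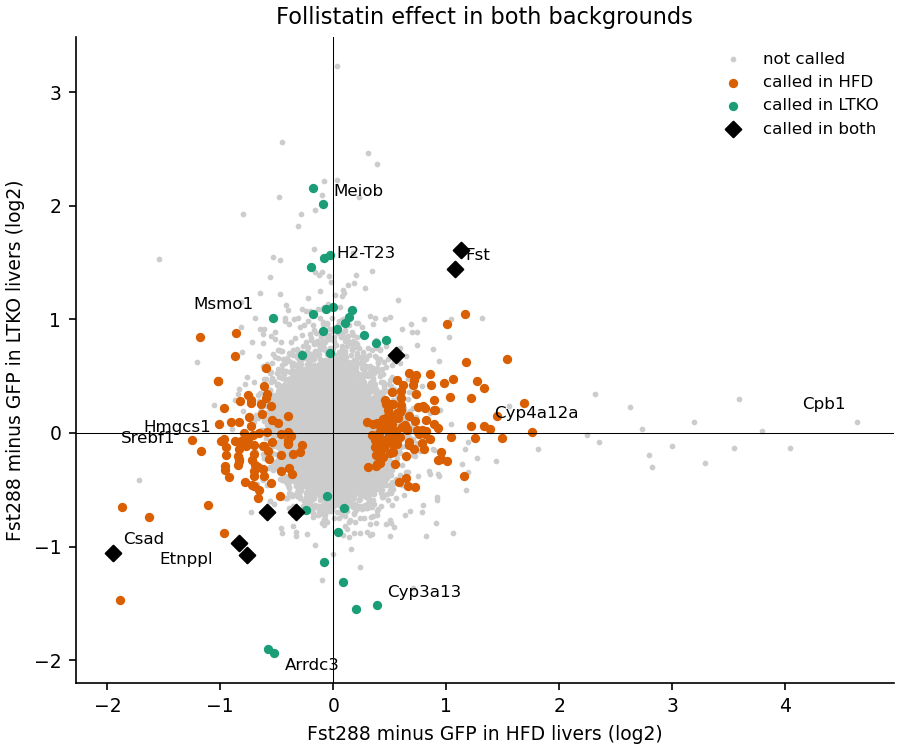
Log2 change with FST288 in HFD livers (x axis) against LTKO livers (y axis), with a point per gene, colours for genes called in HFD or LTKO livers and diamonds for genes called in both. The diamonds are the 3 genes higher and the 5 genes lower in both backgrounds, and r over all genes is -0.077.

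Averaged over both backgrounds, Mug2 was 3.20-fold, Csad 2.83-fold, Arrdc3 2.35-fold, Etnppl 1.87-fold and Srebf1 1.59-fold lower, with adjusted p from 2.21e-06 to 0.0151. Fst rose 2.40-fold, the steroid hydroxylase gene Cyp17a1 2.15-fold, Onecut1 2.13-fold, Acacb, the gene of the mitochondrial acetyl-CoA carboxylase, 1.83-fold and the acute phase gene Orm2 1.77-fold, with adjusted p from 0.00199 to 0.0313. The calls of Acacb and Orm2 were each lost in 7 of 10 leave-one-out fits. By limma, Inhba rose by 0.71 (adjusted p = 0.0404) and Inhbe, the activin E subunit gene, fell by 0.46 (adjusted p = 0.0439). Both calls were lost in 8 of 10 leave-one-out fits, with adjusted p from 0.0524 to 0.137 for Inhba and from 0.0753 to 0.138 for Inhbe. In this contrast 138 genes passed by limma, 71 higher and 67 lower (61 and 69 with quantile normalization), and 2075 had an unadjusted p under 0.05. The count was 83 and 71 without HFD GFP replicates 2 and 3, 81 and 62 without HFD FST288 replicates 2 and 3, 237 without LTKO FST288 replicate 1, 39 with the acinar covariate and 15 without both acinar-high arrays. With the acinar covariate or without both acinar-high arrays, no change of a called gene named here shrank by over 1.5 times. These genes were picked by calls on all arrays, so stable sizes were largely fixed by that choice. Of the 12 genes named here 6 were called in every leave-one-out fit. The calls lost were 4, 4 and 5 without HFD GFP replicates 1, 2 and 3, 2, 3 and 5 without HFD FST288 replicates 1, 2 and 3, 4 and 3 without LTKO GFP replicates 1 and 2, and 2 and 1 without LTKO FST288 replicates 1 and 2.

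Among lists in the averaged effect, 9 acute phase genes rose and 1 fell adjusted over the list alone (camera up, adjusted p = 5.92e-06; adjusted p = 0.158 with an estimated correlation). The glycolysis list was called up with 2 of 15 members higher, 3 adjusted over the list alone (adjusted p = 0.000196; adjusted p = 0.114 with an estimated correlation). The pericentral markers were called down with 2 of 12 lower, 4 adjusted over the list alone (adjusted p = 0.000621; adjusted p = 0.114 with an estimated correlation). The FoxO1-responsive list was called up with 3 of 25 higher and 1 lower, 9 and 1 adjusted over the list alone (adjusted p = 8.24e-05; adjusted p = 0.206 with an estimated correlation). Without Fst 2 of 24 were higher, 8 adjusted over the list alone (adjusted p = 0.000963; adjusted p = 0.287 with an estimated correlation). The activin and BMP target list was called down with 1 of 25 lower, and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.0134; adjusted p = 0.153 with an estimated correlation), and not without LTKO FST288 replicate 1 (adjusted p = 0.0788). The interferon list was called up with none of 35 past limma's test and 11 higher adjusted over the list alone (adjusted p = 5.97e-10; adjusted p = 0.249 with an estimated correlation). MHC class I was called up with 1 of 11 higher, 3 adjusted over the list alone (adjusted p = 5.65e-08; adjusted p = 0.22 with an estimated correlation). The macrophage list was called up with 1 of 19 higher adjusted over the list alone (adjusted p = 5.92e-06; adjusted p = 0.436 with an estimated correlation), and not without LTKO FST288 replicate 2 (adjusted p = 0.283), the array on which these 3 lists were high. The acinar list was called up with a median change of 1.52 and no member past the threshold, also adjusted over the list alone (adjusted p = 3.91e-05; adjusted p = 0.402 with an estimated correlation). Its genes were high on HFD FST288 replicates 2 and 3. The acinar list was not called without these arrays or with the acinar covariate (camera, adjusted p = 0.972 with the covariate). That outcome was fixed in advance, since both settings were built from its markers. Camera called 21 of 47 lists, 15 up and 6 down, none with an estimated correlation, and fry called 8.

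The fourth comparison asks where the follistatin effect differed between LTKO and HFD livers, as a test of the difference itself. Msmo1, Sqle and Hmgcs1, enzymes of cholesterol synthesis, had effects higher in LTKO livers by 1.55, 1.41 and 0.80 on the log2 scale (adjusted p = 0.00654, 0.0413 and 0.0227). Their list of 19 was called up with 3 members higher, 7 adjusted over the list alone (adjusted p = 1.29e-06; adjusted p = 0.527 with an estimated correlation). The effect was also higher in LTKO livers in Meiob (2.10), H2-Q4 (1.66), H2-T23 (1.62), the interferon-inducible gene Ifi204 (1.42), the pericentral gene Oat (0.89) and Csad (0.90, adjusted p = 0.0495), the last chosen after its value was seen. With the mean of its clusters the difference in H2-Q4 was 0.82 (limma, adjusted p = 0.196). The calls of Sqle and Hmgcs1 were each lost in 6 of the 10 leave-one-out fits, and those of H2-Q4 and H2-T23 in 6 and 8. LTKO FST288 replicate 2 stood apart in MHC and interferon genes. Without it the difference was 1.24 in H2-Q4 and 1.14 in H2-T23, and without replicate 1 it was 2.08 and 2.11. The difference in Ifi204 was not called without replicate 2 (adjusted p = 0.0879), and its group means, 1.57 to 2.56, lie under the array medians of named genes, as does the LTKO GFP mean of Meiob. The effect was lower in Cyp3a13 (-1.91), Arrdc3 (-1.42), Slc25a30 (-1.30), Cyp4a12a (-1.27) and Il1r1 (-1.12), with adjusted p from 0.00034 to 0.0495 by limma. Arrdc3 and Il1r1 each lost the call in 8 of the 10 leave-one-out fits. For Srebf1 the difference was 1.01 (adjusted p = 0.0882) and for Fst 0.37 (adjusted p = 0.662), the last 0.09 without HFD FST288 replicate 2 and 0.60 without replicate 1. In all, 48 genes passed by limma, 26 with a higher and 22 with a lower effect in LTKO livers, and 2795 had an unadjusted p under 0.05. The count was 15, 13 and 15 without HFD GFP replicates 1, 2 and 3, 85, 14 and 11 without HFD FST288 replicates 1, 2 and 3, 30 without LTKO GFP replicate 2 and 266 without LTKO FST288 replicate 1. It was 1 with the acinar covariate, where 22 of the 23 named calls were lost. With the covariate or without both acinar-high arrays, none of these named changes shrank by over 1.5 times. The genes were picked by calls on all arrays, which largely fixed this outcome. Of 23 genes called and named for this contrast, 6 were called in every leave-one-out fit, and Csad in none of the 10. Calls lost were 14, 16 and 15 without HFD GFP replicates 1, 2 and 3, 5, 15 and 17 without HFD FST288 replicates 1, 2 and 3, 9 and 14 without LTKO GFP replicates 1 and 2, and 1 and 10 without LTKO FST288 replicates 1 and 2.

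The fifth comparison sets LTKO GFP against HFD GFP livers, which differ in genotype and may differ in diet and collection. Fatty acid oxidation genes were higher in LTKO livers: 23 of 29 rose and none fell by limma, 25 adjusted over the list alone, with Cyp4a14 46.6-fold, Acot1 14.5-fold, Cyp4a31 12.3-fold, Pdk4 12.7-fold and Ehhadh 8.46-fold higher (camera adjusted p = 3.06e-29; adjusted p = 0.00954 with an estimated correlation). Fgf21, a hormone of fasting, was 8.73-fold higher. Fatty acid synthesis genes were lower: 19 of 24 fell and 2 rose, 20 and 2 adjusted over the list alone, with Thrsp 29.2-fold, Lpin1 20.1-fold, Fasn 6.50-fold, Acss2 5.65-fold, Scd1 3.87-fold and Srebf1 3.30-fold lower (adjusted p = 1.53e-21; adjusted p = 0.0721 with an estimated correlation). In cholesterol synthesis 16 of 19 fell, the same number adjusted over the list alone, with Msmo1 5.92-fold, Sqle 4.34-fold, Nsdhl 3.46-fold and Hmgcs1 2.02-fold lower (adjusted p = 7.16e-18; adjusted p = 0.0721 with an estimated correlation).

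The gluconeogenesis list leaned downwards in LTKO livers. Of its 18 members 8 fell, 1 rose and 9 did not pass, with 9 lower and 1 higher adjusted over the list alone (adjusted p = 0.000807; adjusted p = 0.164 with an estimated correlation). The glucose transporter gene Slc2a2 fell by 1.55, the glucose-6-phosphate transporter gene Slc37a4 by 1.39, G6pc by 0.65 (adjusted p = 0.0151) and Pck1 by 0.52 (adjusted p = 0.0072) on the log2 scale. Without LTKO GFP replicate 1 the changes were -0.35 in G6pc (adjusted p = 0.214) and -0.40 in Pck1 (0.096), and without HFD GFP replicate 3 that of G6pc was -0.61 (0.0537). Of 15 glycolysis genes 4 fell and 2 rose, the same adjusted over the list alone, and the list was not called (adjusted p = 0.171); Pklr, the last enzyme of glycolysis, was 8.15-fold lower. Of 25 FoxO1-responsive genes 10 fell and 6 rose, 11 and 6 adjusted over the list alone; the list was not called (adjusted p = 0.308), its median was -0.18 and its mean 0.10. Cdkn1a (2.66) and Angptl8 (1.60) were higher and Ddit4 (-1.40) lower.

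Antioxidant, drug and clock genes differed between the backgrounds too. In the glutathione and NRF2 list 13 of 25 rose and 1 fell, 15 and 1 adjusted over the list alone, with Gclc (1.51), Ephx1 (1.48) and Nqo1 (1.34) higher (adjusted p = 3.56e-08; adjusted p = 0.0392 with an estimated correlation). In the xenobiotic list 12 of 25 rose and 2 fell, 12 and 5 adjusted over the list alone, with Cyp3a11 at 1.88 (adjusted p = 0.000414; adjusted p = 0.0721 with an estimated correlation). Of 19 clock genes 12 fell and 5 rose, the same adjusted over the list alone (adjusted p = 2.61e-06; adjusted p = 0.0857 with an estimated correlation). Arntl was 9.70-fold higher and Dbp 8.45-fold, Wee1 6.73-fold and Nr1d2 3.96-fold lower, with Wee1 at 3.16 in LTKO GFP livers, near the array medians of named genes. Among 35 interferon-stimulated genes 8 fell, 18 adjusted over the list alone, with Ifit1 (-1.88), Ifih1 (-1.75) and Bst2 (-2.00) lower (adjusted p = 3.72e-08; adjusted p = 0.343 with an estimated correlation). Of 11 MHC class I genes 3 fell, H2-T23 (-2.00) among them, and 5 adjusted over the list alone (adjusted p = 0.000303; adjusted p = 0.442 with an estimated correlation). Without LTKO GFP replicate 1 the change in Bst2 was -1.04 (adjusted p = 0.131).

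Outside these lists, Serpina1d, a secreted protease inhibitor, was 95.3-fold lower in LTKO livers at 5.77 ± 0.03 against 12.35 ± 0.04 (SD, n = 2 and 3), and the membrane peptidase gene Mme was 32.3-fold lower. Mug2 was 19.0-fold and the uridine phosphorylase gene Upp2 14.3-fold lower, while Ctse was 24.8-fold and the leptin receptor gene Lepr 12.7-fold higher. The lower group mean was 2.70 for Mme and 2.63 for Ctse, under the array medians of named genes, where folds are not exact. Csad was 6.81-fold and Etnppl 2.29-fold higher in LTKO GFP than in HFD GFP livers, values chosen after they were seen. Igfbp2 was 2.22-fold, Inhbc 2.95-fold and Inhbe 1.84-fold higher. In all, 2902 genes differed by limma, 1483 higher and 1419 lower (1431 and 1483 with quantile normalization, 1261 and 1596 with median centring), and 5582 had an unadjusted p under 0.05. The median of 73 small nucleolar RNA genes was 7.41 and 7.89 on the LTKO GFP arrays and 6.12 to 6.61 on the HFD GFP arrays. Camera called 19 of 47 lists, and 2 of them also with an estimated correlation, fatty acid oxidation and glutathione. The count was 1870 without LTKO GFP replicate 1, which ended 5 of the 62 calls named for this contrast, those of Irs2, G6pc, Pck1, Bst2 and Selenbp2 (adjusted p = 0.0725). Without HFD GFP replicate 3, the call of G6pc was lost.

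**Figure D4:**
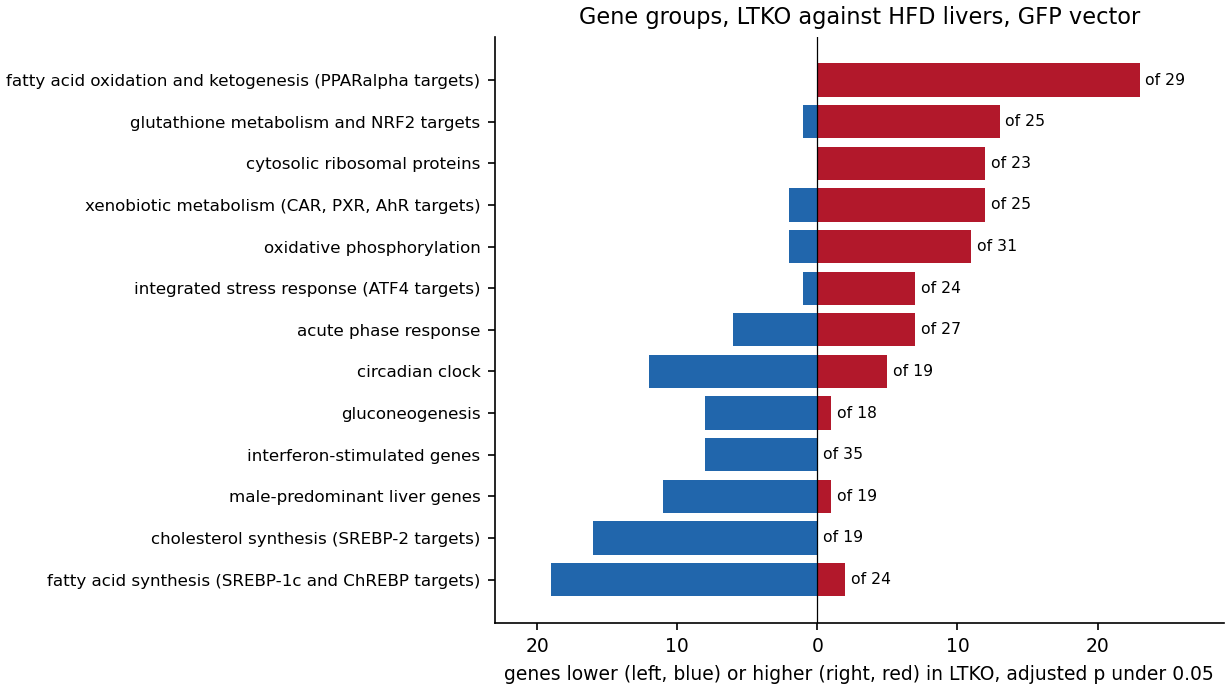
Number of measured genes in each list that were lower (left) or higher (right) in LTKO GFP than in HFD GFP livers at an adjusted p under 0.05. Fatty acid oxidation has 23 genes higher of 29, and fatty acid synthesis has 19 lower of 24.

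**Figure D5:**
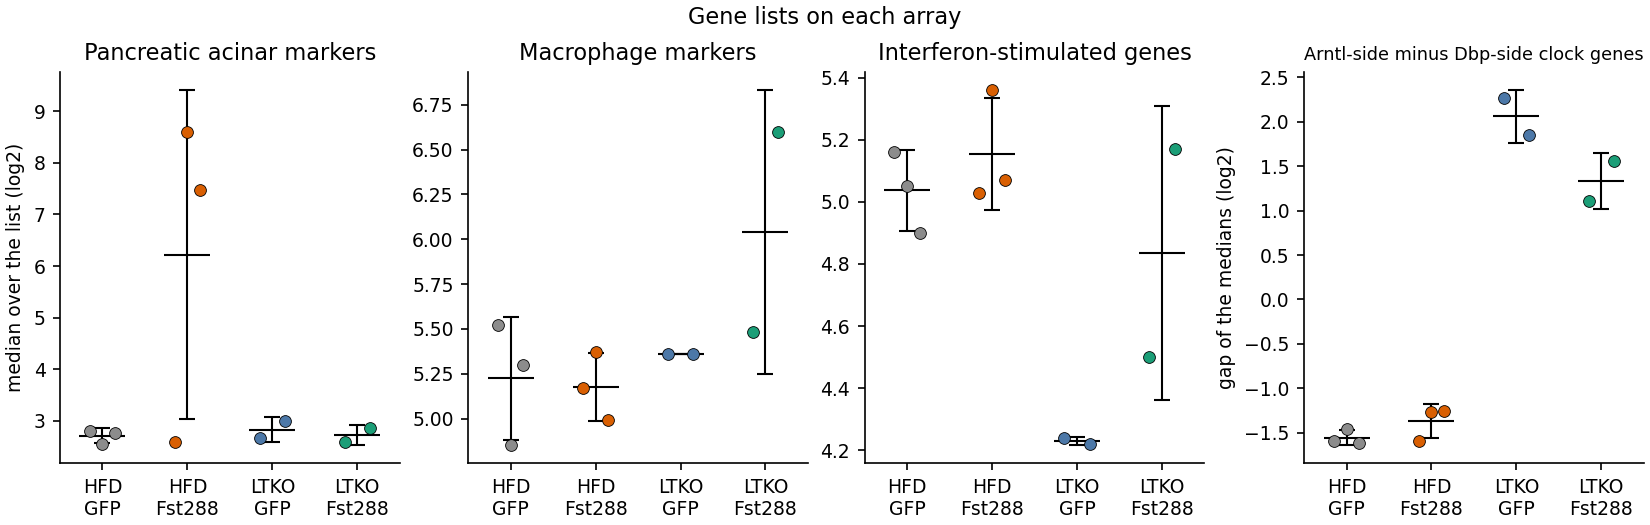
Median log2 value of the acinar, macrophage and interferon lists, and the clock gap, meaning the median of clock genes on the side of Arntl minus that of clock genes on the side of Dbp, with a point per array and the group mean ± SD. The acinar median is 8.59 and 7.48 on HFD FST288 arrays 2 and 3, the macrophage median is 6.60 on LTKO FST288 array 2, and the clock gap is above 1 on the LTKO arrays.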

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

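The tests of the vector raising acinar genes, of a lower share of hepatocytes, of the vector raising interferon-stimulated genes, of the time of day and of other splits of the arrays were chosen after the results were seen. So were the spreads set against the second acinar list and the interferon share, and the comparisons of neighbouring genes without gene families and among the strongest genes.

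The difference of the follistatin effect between LTKO and HFD livers passed limma's test in 48 genes and is listed here for that reason. The effect was higher in LTKO livers in Meiob (2.10), Rasgef1b (1.97), Resf1 (1.74), H2-Q4 (1.66), H2-T23 (1.62), Nipal1 (1.55), Msmo1 (1.55), Ifi204 (1.42), Sqle (1.41) and Mlh3 (1.34), as log2 differences. With the mean of its clusters H2-Q4 was at 0.82 and not called (limma, adjusted p = 0.196). The effect was lower in Cyp3a13 (-1.91), Ifnl3 (-1.75), Arrdc3 (-1.42), Glt1d1 (-1.40), Serpina4-ps1 (-1.32), Slc25a30 (-1.30), Cyp4a12a (-1.27), Pex26 (-1.20), Slc22a28 (-1.13) and Il1r1 (-1.12). The LTKO FST288 mean of Ifnl3, 3.08, lies under the array medians of named genes, as do the LTKO GFP mean of Meiob and the group means of Ifi204. Their differences are not exact. Without HFD FST288 replicate 3 the count of 48 was 11, and without LTKO FST288 replicate 1 it was 266; it was 15, 13 and 15 without HFD GFP replicates 1, 2 and 3, 85 and 14 without HFD FST288 replicates 1 and 2, and 30 without LTKO GFP replicate 2.

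By camera 13 lists differed in this contrast, and none did with an estimated correlation, where adjusted p ran from 0.493 to 0.713. Median differences above 0 were those of cholesterol synthesis (0.37), interferon-stimulated genes (0.46), MHC class I (0.68), female-predominant genes (0.20), pericentral markers (0.28), macrophage markers (0.69) and T and NK cell markers (0.22). Those below 0 were glycolysis (-0.08), the unfolded protein response (-0.37), male-predominant genes (-0.49), oxidative phosphorylation (-0.26), heat shock proteins (-0.19) and acinar markers (-3.29).

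Transcript clusters that the gene table does not list were outside the comparisons of named genes. Of these 16010 clusters, 17 passed for FST288 in HFD livers, 7 in LTKO livers, 9 for the average effect, 3 for the difference and 842 for LTKO GFP against HFD GFP.

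Acinar genes were high on HFD FST288 replicates 2 and 3, with marker medians of 8.59 and 7.48. A vector that raises them in any liver is argued against by the other 3 FST288 arrays, whose highest median, 2.86, lay below the highest of the GFP arrays, 3.00. That these 2 arrays alone carry the HFD follistatin effect is argued against, since in 200 genes picked from them at least 83.5% went the same way on HFD FST288 replicate 1 against a held-out GFP array, with a smaller median size of 0.40 to 0.48 against 0.79 to 0.80. Pancreatic tissue carried over at dissection may account for the acinar genes and stays open: Klk1, Reg1, Sycn and Pnliprp1 of a second list of 23 were up by 3.48 to 6.31, while the lower median over that list was 0.816, with a bootstrap SE of 0.47. The bound set before that test, a median under 1, was met, but by less than this spread. Of the 23 genes 9 were up by over 1 on both arrays, and of 14 islet genes 0 were. Of the 9 markers in the first list 8 were, with median rises of 5.51 and 4.29. The enzymes Ctrc (0.36 and 0.38), Try5 (0.18 and 0.25) and Prss3 (0.20 and 0.30) were not, and read at most 3.14 on every array. Amy1 of the second list read at least 7.95 on every array. Genes at such levels on all arrays cannot decide the question, and no further biological explanation was tested.

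Macrophage, interferon and MHC genes were high on LTKO FST288 replicate 2. A lower share of hepatocytes in that sample is argued against, since against replicate 1 the 19 macrophage markers were up by a median of 1.02 and the endothelial markers by 0.03, a gap of 0.992 where the other pairs of arrays of a group had a root mean square of 0.247. An effect of the FST288 vector on interferon genes could not be told apart from a state of this 1 liver: on replicate 1, 17 of 35 interferon-stimulated genes (48.6%) lay above both LTKO GFP arrays, against 31.3% of all genes, and on replicate 2, 29 of 35. The bound written for this test, under 50%, was met by less than the binomial spread of 35 genes. Macrophages in a different state or number in that liver stay open as well, and were not tested further.

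Clock and lipid genes differed between LTKO and HFD livers. DNA of another strain around the deleted genes was predicted to make calls there at least 2 times as frequent, which is argued against. In the gene order of GRCm38.p6, 13 of 120 genes beside Irs1, Irs2 and Foxo1 were called. This is 10.8% against 13.1% of all placed genes (Fisher exact test, two-sided, p = 0.587). The shares were 12.5% beside Irs1, 17.5% beside Irs2 and 2.5% beside Foxo1. Such DNA changing only a few neighbours would not move the pooled share and stays open. A strain difference over the genome stays open. The excess of called genes beside other called genes was 3.43 times that of as many top genes of the HFD follistatin contrast. These were the 2902 with the smallest p there, most of them not called. The ratio meets the bound written before, but the HFD share, 14.6%, lay under the 15.3% that random genes reached. It therefore divides by an excess that random genes also gave. Without gene family pairs the shares were 16.0% against 11.7%. Among the 221 strongest genes of each they were 5.43% against 4.07% with all pairs and 1.36% against 2.26% without family pairs. The last 2 lay within the 3.17% that random genes reached. A different time of day at collection could account for the clock genes and cannot be told apart from the genotype, since the clock gap was 1.11 to 2.27 on the LTKO arrays and -1.62 to -1.25 on the HFD arrays, 2.36 apart. The genotype and the diet, which the design names or leaves unstated, stay open and were not tested.

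Other splits of the arrays were counted. For FST288 in HFD livers 10 splits of the 6 arrays exist, too few for a share under 0.05; the real split called 221 genes, the highest other split 0, and 1 split called as many as the real one, itself. For the average effect 60 splits within backgrounds exist. The real split called 138 genes and the highest other split 62, so 1 of 60 called as many, a share under 0.05. Splits with another HFD arm called at most 4 genes, so the count rests mainly on the HFD arm, whose 10 splits are too few. Both acinar-high arrays lie in that arm, and the splits cannot tell the vector apart from other traits of its arrays.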

How the results depend on the processing

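The acinar covariate, the fit without the 2 acinar-high arrays and the lists without Fst were chosen after seeing the data; all other settings were planned. A robust fit, quantile normalization, median centring, filters on dim genes and probe means kept the 5 counts of genes within 1.5 times of their values. LTKO minus HFD averaged over both vectors called 3840 genes and kept all 62 named calls. Changes shrank by over 1.5 times in H2-T23 (-2.00 to -1.19), Hmgcs1 (-1.02 to -0.62) and Pck1 (-0.52 to -0.29). The cause of the changes below was not tested, except where fewer arrays or a stricter or looser threshold show it.

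Counts of genes for FST288 in HFD livers (221), in LTKO livers (37), averaged (138) and for the difference (48) moved as follows. With only the arrays compared, HFD livers gave 411 and LTKO livers 0 genes by limma (1665 at an unadjusted p under 0.05). Without an intensity trend they were 101, 16, 52 and 3, and with all clusters tested 80, 15, 29 and 6. At an adjusted p under 0.10 they were 405, 58, 214 and 155. A change of at least 1.5-fold left 141 in HFD livers, 59 averaged and 1757 for LTKO GFP against HFD GFP (2902). Array weights gave 22 in LTKO livers, and a replicate block 28 for the difference; effects of equally numbered arrays did not run together (r of 0.008, -0.007 and -0.010 in HFD livers, -0.068 in LTKO livers). The acinar covariate gave 35, 23, 39 and 1, and the fit without the acinar-high arrays 6, 16, 15 and 1.

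Lists called by camera (11 in HFD livers, 15 in LTKO livers, 21 averaged) came to 0, 0 and 0 with an estimated correlation and 2, 0 and 8 with fry. In HFD livers both acinar settings gave fewer, 7 with the covariate, where the loss of the acinar list was fixed in advance. With Fst left out of the lists they were 9, 16 and 21, and secreted hepatokines were called down in LTKO livers (adjusted p = 0.0205; adjusted p = 0.348 with an estimated correlation; 0.124 with Fst). The correlation of the effects across genes, -0.077, was -0.034 for genes above the median level, -0.0076 with the acinar covariate and 0.0043 without the acinar-high arrays.

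Leaving out each array in turn gave 80 to 307 genes in HFD livers, 21 to 237 in LTKO livers, 62 to 237 averaged, 11 to 266 for the difference and 1870 to 3037 for LTKO GFP against HFD GFP. Lists ranged from 10 to 13, 12 to 17 and 17 to 21, and the correlation from -0.099 to -0.049.

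Of the values of named genes, 2508 under planned settings other than leave-one-out fits had the same direction and side of the threshold. In these settings 272 lost and 13 gained a call, and 1 turned. Leave-one-out fits gave 1782, 365, 20 and 13, and the acinar settings 261, 167, 2 and 6. The values that turned are all of genes that were not called. With probe means Irs1 in LTKO livers (0.04) was -0.0564. With the acinar covariate Pck1 in HFD livers (-0.01) was 0.103, Fstl3 in HFD livers (0.04) -0.0507 and the difference in Fst (0.37) -0.173; without the acinar-high arrays they were 0.0845, -0.0377 and -0.0879. Leave-one-out values in HFD livers ran from -0.0659 to 0.0528 in Pck1 (above 0 without HFD GFP replicate 2, at 0.0519, and HFD FST288 replicate 2), -0.0582 (without HFD GFP replicate 2) to 0.107 in Fstl3, -0.188 to 0.0121 (without HFD FST288 replicate 1) in Igfbp1, -0.251 to 9.67e-05 (without HFD GFP replicate 3) in Fgf21 and -0.17 to 0.0153 (without HFD GFP replicate 2) in Irs1. In LTKO livers they ran from -0.741 to 0.244 (without LTKO GFP replicate 2) in Inhbb, -0.185 to 0.094 in Fstl3 (above 0 without LTKO GFP replicate 2, and without LTKO FST288 replicate 2, at 0.0677), -0.126 to 0.202 in Irs1 (below 0 without LTKO GFP replicate 2, at -0.00372, and LTKO FST288 replicate 1) and -0.546 to 0.301 in Irs2 (above 0 without LTKO GFP replicate 2, and without LTKO FST288 replicate 1, at 0.206). Signals near the array's background cannot show small changes, and the lowest value in the table was 0.64.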

Other observations

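LTKO GFP livers differed from HFD GFP livers in gene groups beyond metabolism, stress defence and the clock. Ribosomal protein genes were higher: 12 of 23 rose and 15 adjusted over the list alone, with Rpl19 up by 0.89 and Rplp1 by 0.78 on the log2 scale (limma's camera, adjusted p = 1.59e-09; adjusted p = 0.0857 with an estimated correlation). In oxidative phosphorylation 11 of 31 rose and 2 fell, the same adjusted over the list alone, with Cox4i1, a subunit of cytochrome oxidase, up by 0.88 (adjusted p = 0.00366; adjusted p = 0.45 with an estimated correlation). Of 24 targets of the integrated stress response 7 rose and 1 fell, 8 and 1 adjusted over the list alone (adjusted p = 0.00145; adjusted p = 0.0857 with an estimated correlation); Asns, which makes asparagine, was 6.15-fold, from 3.16 near the array medians of named genes, and the transcription factor Atf5 4.58-fold higher. Of 21 hepatokine genes 5 rose and 1 fell, 8 and 1 adjusted over the list alone (adjusted p = 0.00385; adjusted p = 0.0857 with an estimated correlation). Of 25 activin and BMP targets 7 rose and 1 fell, 7 and 2 adjusted over the list alone (adjusted p = 0.0233; adjusted p = 0.12 with an estimated correlation).

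Sex-biased and zonal genes also differed between these livers, all from males. Of 19 male-predominant genes 11 fell and 1 rose, 12 and 3 adjusted over the list alone, with Selenbp2 13.3-fold, Cyp2u1 7.70-fold, Serpina1e 5.91-fold and C9 2.25-fold lower in LTKO livers (adjusted p = 3.41e-06; adjusted p = 0.343 with an estimated correlation). The call in Selenbp2 was lost without LTKO GFP replicate 1 (log2 change -2.18, adjusted p = 0.0725). Of 17 female-predominant genes 4 rose, and 5 rose and 1 fell adjusted over the list alone, with Acot3 6.76-fold and Abcd2 3.45-fold higher (adjusted p = 0.0426; adjusted p = 0.211 with an estimated correlation). Of 9 periportal markers 5 fell, 6 adjusted over the list alone, with Cyp2f2 1.77-fold lower (adjusted p = 0.00129; adjusted p = 0.159 with an estimated correlation). Stellate cell markers were called up with 2 of 13 higher and 1 lower, 4 and 1 adjusted over the list alone (adjusted p = 0.0338; adjusted p = 0.343 with an estimated correlation). Adipocyte markers were called down with 2 of 9 lower, also adjusted over the list alone (adjusted p = 0.0477; adjusted p = 0.184 with an estimated correlation).

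Small nucleolar RNA genes, 73 of them, had median values of 6.12, 6.61 and 6.20 on the HFD GFP arrays, 6.78, 6.98 and 6.76 on HFD FST288, 7.89 and 7.41 on LTKO GFP and 7.64 and 7.54 on LTKO FST288. The first principal component of all genes held 46.7% of the variance and the next 12.7%.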
